A study of Danio rerio with 20 samples.

How the data were processed

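Polyadenylated RNA of isolated adult zebrafish cardiomyocytes was sequenced in 20 bulk libraries of 10 groups, wild type or kita/kitb mutant, untouched or at 2, 5, 7 or 14 days after resection of about 20% of the ventricular apex, each library from 8 pooled ventricles. Per the labels, the authors checked reads with FastQC and counted them with featureCounts on danRer10, without versions. The aligner and annotation are not given in the sources used here. The deposited matrix held CPM per gene symbol and library. Each column summed to 1000000 over 14781 genes, and 3 further lines without gene names were left out. Each column's values were whole multiples of a step of 1 read (100% whole within 0.1 read), from which 14.6 to 31.7 M reads per library were recovered. Counts of reads are not counts of molecules, so a floor of 3 reads covers counting error only. 11 symbols looked like dates and were kept as given. No annotation of the build was held, so positions of genes are not given. The labels of the 14 dpi samples gave another day in 1 field, and 14 was used as in the sample titles.

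CPM were divided by median-ratio factors (0.881 to 1.18, from 11000 genes above 0 in all libraries) to give scaled CPM. Genes with CPM of 1 or more in at least 2 libraries were tested, 10914 of 13956 above 0. log2(scaled CPM + 1) went into a limma-trend fit (limma 3.58.1, R 4.3.3) of 10 group means with 10 residual degrees of freedom (16.2 in total with the prior). The 17 contrasts were each time against untouched in wild type (4) and in mutants (4), mutant against wild type at each time (5), and the difference of the responses (4). Tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. With 2 libraries per group, no permutation test of a pair of groups can pass that threshold.

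Before the data were examined, 32 gene lists were fixed, 30 of them with 3 or more tested members. Each was tested in each contrast with camera at a preset correlation of 0.01, adjusted over all 510 tests. With that setting 244 tests passed. With a correlation estimated from the residuals camera called 0, the lowest adjusted p was 0.242, and 51 tests had an unadjusted p under 0.05. Values of a list are the median log2 difference of its members. The rule for named genes, set before the data were examined, took kita, kitb, kitlga and kitlgb, the 3 largest rises and falls of each contrast with an adjusted p under 0.05, a mean of 5 scaled CPM or more in the higher group, an approved-looking symbol and, outside the differences of responses, libraries apart, and up to 4 members per described list by adjusted p. Which lists and members to describe was chosen after the values were seen, and genes whose call was lost without 1 library are mostly left out of the report. Some single-gene results are not reported here.

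The settings tried were CPM as deposited, quantile normalization, no filter, a filter of CPM 5, a pseudocount of 0.25, a replicate block, each genotype alone and leaving out each library in turn. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood test with TMM) on recovered reads, the 3 near-identical mutant pairs averaged, and leaving out libraries for lists other than the cell cycle list. Pairs were called near-identical at a mean chi-square per gene under 10, over genes with 20 or more reads, a limit set after the values were seen. The calls were tested on simulated data. With true groups equal and these pairs simulated as repeats of 1 preparation, the fit made up to 471 false calls (mutants at 7 dpi), and 0 with the pairs averaged.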

Results

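RNA came from cardiomyocyte preparations of wild-type zebrafish and kita/kitb mutants, with mutations in both copies of the kit receptor tyrosine kinase gene. Ventricles were untouched or taken 2, 5, 7 or 14 days after resection of 20% at the apex (dpi). Each of the 20 libraries pooled 8 ventricles, with 2 per group of genotype and time. Assigned reads ranged from 14.6 to 31.7 M, with the mutant pair of 2 dpi deepest (31.7 and 29.3 M). Only that pair carried a lane 7 label, and all other libraries lane 8. Mutant libraries in lane 8 reused sample indices of wild-type ones, so the genotypes cannot have shared a lane of a single run. Genotype and run thus cannot be told apart at a single time point. Levels are scaled CPM (CPM divided by a library factor), as mean ± SD of the 2 libraries of a group, and "a against b" gives the later time or the mutant first. Differences are log2 ± SE from limma, and a gene given without a p passed an adjusted p of 0.05. A count "of" a list covers its tested members, and its median is of their log2 differences. Each p of a list is from camera with a preset correlation of 0.01, and with an estimated correlation no list passed (lowest adjusted p = 0.242). Where leaving out 1 library moved a count by over 1.5 times, such a count is given.

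In 3 mutant groups (untouched, 2 and 7 dpi) the libraries of a pair were nearly identical. Their mean chi-square per gene was 1.98 to 3.87, where read sampling alone gives about 1, against 15.4 to 57.8 in the other 7 groups. The labels do not say whether those pairs came from separate preparations. Counts of genes are therefore also given with the 3 pairs averaged (for wild-type time course lists only if moved by over 1.5 times). Other p, SD and SE keep both libraries, may be too small if these are repeats, and measure the spread among these 20 libraries only.

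**Figure D1:**
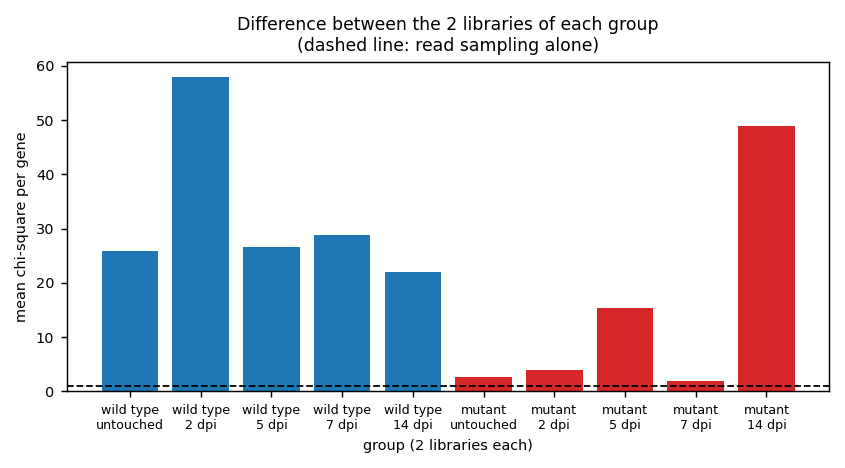
Mean chi-square per gene between the 2 libraries of each group (vertical axis, no unit), with a dashed line at the value read sampling alone gives. The mutant bars for untouched, 2 dpi and 7 dpi stand at 2.59, 3.87 and 1.98, and the other 7 bars lie between 15.4 and 57.8.

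The receptors and ligands of the kit pathway were expressed at low levels. kita, a kit receptor gene, had 6 to 29 reads per library, which gave 0.810 ± 0.325 scaled CPM in wild type and 0.767 ± 0.381 in mutants (SD, n = 10 libraries each). At 5 dpi it was lower in mutants than in wild type (0.408 ± 0.0492 against 1.09 ± 0.137 scaled CPM, log2 -0.57 ± 0.21, adjusted p = 0.040) and than in untouched mutants (adjusted p = 0.045), and in wild type it was lower at 2 dpi than untouched (adjusted p = 0.031). These calls were lost with the pairs averaged (adjusted p = 0.080, 0.17 and 0.061) and without some single libraries. kitb, the other receptor gene, had 0 to 8 reads, and kitlgb, a kit ligand gene, had 0 to 3. A count of 0 allows up to 3 reads, or 0.0947 to 0.205 CPM depending on the library. kitlga, the other ligand gene, had 81 to 409 reads, with 9.73 ± 2.18 scaled CPM in wild type and 8.78 ± 2.43 in mutants. At 5 dpi it was lower in mutants (5.04 ± 1.02 against 10.7 ± 1.12, log2 -0.97 ± 0.17, adjusted p = 4.0e-04). It was lower at 7 dpi too (log2 -0.62 ± 0.17, adjusted p = 0.013) and higher at 2 dpi (log2 0.51 ± 0.17, adjusted p = 0.017), but these 2 calls were lost with the pairs averaged (adjusted p = 0.12 and 0.094) and without some single libraries. The receptor levels were too low to check the genotype labels from the transcripts.

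The wild-type time course asks how the preparations changed after apex resection. At 2 dpi col11a1b, a fibrillar collagen chain, stood at 149 ± 11.8 against 2.28 ± 0.901 scaled CPM in untouched hearts (log2 5.54 ± 0.20, adjusted p = 2.2e-11), and fn1a, which encodes fibronectin, rose 31.4-fold (log2 4.97 ± 0.15, adjusted p = 1.8e-12). lipg, endothelial lipase, rose as well (98.0 ± 4.68 against 2.63 ± 1.37, log2 4.82 ± 0.24). Falls included f13a1a.1, a coagulation factor XIII subunit (5.86 ± 1.67 against 199 ± 33.4, log2 -4.88 ± 0.44, adjusted p = 2.6e-07), elnb, an elastin gene (log2 -3.37 ± 0.37), and ctrb1, a chymotrypsin precursor (log2 -3.38 ± 0.67). In all, 2881 genes were higher and 2753 lower, 5634 of 10914 tested (4951 with the pairs averaged).

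Cell cycle genes rose at 2 dpi, 65 of 82 higher and 0 lower (67 and 0 adjusted over the list alone). The median was 1.05 (adjusted p = 4.9e-20). The mitotic cyclin gene ccnb1 reached 39 ± 5.06 against 1.76 ± 0.0187 scaled CPM, and top2a, a DNA topoisomerase of dividing cells, rose 6.87-fold (log2 2.78 ± 0.14). Epicardium and fibroblast genes rose, 30 of 41 higher and 4 lower (30 and 4 adjusted over the list alone), among them the growth factor gene mdka (log2 3.72 ± 0.13) and wt1b, a transcription factor of the epicardium (log2 4.05 ± 0.17). The median was 0.90 (adjusted p = 4.0e-08). Proteasome genes rose, 42 of 43 higher and 0 lower (42 and 0 adjusted over the list alone), such as psma5 (log2 0.97 ± 0.09) and psma6l (log2 1.95 ± 0.15). The median was 0.63 (adjusted p = 2.5e-13). By symbol that list holds psmc3ip, which is not a proteasome subunit. Macrophage genes were 18 of 27 higher and 3 lower (18 and 3 adjusted over the list alone), with the perforin-like gene mpeg1.1 2.96-fold up. The median was 1.15 (adjusted p = 0.0021). Without wild-type 2 dpi replicate 1 the macrophage median was 0.56 (adjusted p = 0.090). The inflammatory list had 10 of 24 higher and 2 lower (10 and 2 adjusted over the list alone), with crlf1a, a cytokine receptor-like factor (log2 2.43 ± 0.18), and ptgs2a, a prostaglandin synthase (log2 2.1 ± 0.14). The median was 0.62 (adjusted p = 0.012). Its call was lost without wild-type 2 dpi replicate 1 (median 0.12, adjusted p = 0.29) and on CPM as deposited (adjusted p = 0.12).

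Genes of energy metabolism and contraction fell at 2 dpi. Oxidative phosphorylation had 2 of 91 higher and 84 lower (2 and 84 adjusted over the list alone), with ndufa4 (652 ± 161 against 1672 ± 157 scaled CPM, log2 -1.38 ± 0.14) and uqcrc1, a core subunit of complex III (log2 -0.99 ± 0.12). The median was -0.74 (adjusted p = 8.5e-15). Without wild-type 2 dpi replicate 1 that median was -0.49. Fatty acid oxidation had 0 of 26 higher and 26 lower (0 and 26 adjusted over the list alone), with cpt2, a carnitine palmitoyltransferase (log2 -1.26 ± 0.11), and the fatty acid transporter gene cd36 (0.537 ± 0.208 against 8.89 ± 2.17). The median was -0.90 (adjusted p = 1.6e-10). Sarcomere genes had 0 of 26 higher and 20 lower (1 and 20 adjusted over the list alone), with unc45b, a myosin chaperone (log2 -2.00 ± 0.18), and the M-band gene myom1a (log2 -1.38 ± 0.19). The median was -0.69 (adjusted p = 3.0e-05), with 13 lower without wild-type untouched replicate 2. Endothelium and endocardium genes had 2 of 34 higher and 28 lower (3 and 28 adjusted over the list alone), with the angiopoietin receptor gene tek 2.41-fold and the water channel gene aqp8a.1 3.16-fold lower. The median was -0.74 (adjusted p = 1.1e-07).

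At 5 dpi col11a1b was still high in wild type (171 ± 4.60 against 2.28 ± 0.901 scaled CPM, log2 5.74 ± 0.20, adjusted p = 3.8e-11). nppc, the gene of C-type natriuretic peptide (159 ± 0.616 against 2.58 ± 0.809, log2 5.51 ± 0.25), and the granulin gene grn1 (108 ± 9.34 against 5.65 ± 3.11, log2 4.12 ± 0.64) rose, and cyp1b1, a cytochrome P450 gene, fell (23.6 ± 7.25 against 181 ± 102, log2 -2.80 ± 0.38). Macrophage genes rose, 26 of 27 higher and 0 lower (26 and 0 adjusted over the list alone), such as mpeg1.1 (log2 2.43 ± 0.22) and the complement gene c1qa (log2 2.42 ± 0.28). The median was 1.65 (adjusted p = 5.0e-16). The fibroblast list had 35 of 41 higher and 1 lower (35 and 1 adjusted over the list alone), with the periostin gene postnb at 1289 ± 23.8 against 179 ± 0.170 and mdka 10.4-fold up. The median was 1.09 (adjusted p = 6.4e-20). Inflammatory cytokine genes had 14 of 24 higher and 0 lower (15 and 0 adjusted over the list alone), with csf1a, a macrophage growth factor gene (log2 2.89 ± 0.20), and ptgs2a (log2 2.15 ± 0.14). The median was 1.07 (adjusted p = 2.3e-07), with 9 higher without wild-type untouched replicate 1. Cell cycle genes split, 31 of 82 higher and 12 lower (34 and 15 adjusted over the list alone), with the cytokinesis gene anln higher (log2 1.36 ± 0.14). The median was 0.21 (adjusted p = 0.018). The cell cycle call was lost without wild-type untouched replicate 1 (median 0.16, adjusted p = 0.32), without wild-type 5 dpi replicate 1 (median 0.16, adjusted p = 0.053) and with quantile normalization (adjusted p = 0.10).

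Energy genes stayed lower at 5 dpi. Oxidative phosphorylation had 1 of 91 higher and 85 lower (1 and 85 adjusted over the list alone), such as cox5ab (142 ± 3.16 against 286 ± 43.4 scaled CPM, log2 -1.0 ± 0.13). The median was -0.73 (adjusted p = 4.5e-22). Fatty acid oxidation had 0 of 26 higher and 21 lower (0 and 23 adjusted over the list alone), such as cpt2 (log2 -0.98 ± 0.11) and the electron transfer gene etfb (log2 -0.76 ± 0.11). The median was -0.63 (adjusted p = 4.3e-09). Proteasome genes did not pass as a list (adjusted p = 0.16), and their median and mean differed in sign. The members with the smallest adjusted p, psmb8a (log2 1.71 ± 0.20) and psmb9a (log2 1.49 ± 0.17), encode interferon-inducible immunoproteasome subunits. 1731 genes were higher and 1850 lower, 3581 together (2676 with the pairs averaged). The total was 2213 without wild-type untouched replicate 2 and 2146 without wild-type 5 dpi replicate 1.

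By 7 dpi col11a1b stood at 258 ± 1.28 against 2.28 ± 0.901 scaled CPM (log2 6.33 ± 0.20, adjusted p = 7.8e-12) in wild type, and nppc (log2 5.01 ± 0.25) and the laminin gene lama1 (26.7 ± 5.10 against 0.429 ± 0.121, log2 4.27 ± 0.18) were higher. tnni1d, a troponin I gene, fell (1.13 ± 0.233 against 13.8 ± 2.43, log2 -2.79 ± 0.39, adjusted p = 4.5e-05). Macrophage genes all rose, 27 of 27 higher and 0 lower (27 and 0 adjusted over the list alone), among them mpeg1.1 (log2 2.80 ± 0.22) and cd74b, an MHC class II invariant chain (log2 2.17 ± 0.18). The median was 2.17 (adjusted p = 5.2e-16). Epicardium and fibroblast genes had 35 of 41 higher and 0 lower (35 and 0 adjusted over the list alone), with mdka at 1936 ± 46.0 against 147 ± 10.4 and wt1b at 106 ± 10.8 against 5.04 ± 0.650. The median was 1.48 (adjusted p = 5.8e-23). The macrophage growth factor gene csf1a was 11-fold up. 1914 genes were higher and 1884 lower, 3798 together (3030 with the pairs averaged).

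Oxidative phosphorylation remained below untouched hearts at 7 dpi, 2 of 91 higher and 85 lower (2 and 86 adjusted over the list alone), with uqcrc1 2.32-fold and cox5ab 2.51-fold lower. The median was -0.99 (adjusted p = 1.1e-28). Sarcomere genes had 0 of 26 higher and 18 lower (0 and 19 adjusted over the list alone), such as unc45b (log2 -1.43 ± 0.18) and csrp3, a muscle LIM protein (log2 -1.33 ± 0.18). The median was -0.65 (adjusted p = 2.3e-06), with 9 lower without wild-type untouched replicate 2. Replication and mitosis genes were 15 of 82 higher and 34 lower (18 and 35 adjusted over the list alone), with the replication helicase gene mcm6 lower (22.3 ± 3.24 against 52.2 ± 15 scaled CPM, log2 -1.17 ± 0.19) and the cyclin gene ccnb3 higher (log2 1.15 ± 0.19). The median was -0.20 (adjusted p = 0.032), with 19 lower without wild-type untouched replicate 2. That call was lost without wild-type untouched replicate 2 (median -0.16, adjusted p = 0.28), without wild-type 7 dpi replicate 2 (median -0.27, adjusted p = 0.19) and with a filter of CPM 5 (adjusted p = 0.099). The median was -0.34 and -0.35 without replicate 1 of untouched and of 7 dpi wild type.

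At 14 dpi cell cycle genes lay below untouched wild-type hearts, 0 of 82 higher and 64 lower (0 and 67 adjusted over the list alone). The median was -0.97 (adjusted p = 2.4e-33). Erythrocyte genes fell too, 0 of 15 higher and 3 lower (0 and 3 adjusted over the list alone). The median was -0.57 (adjusted p = 0.019), with 1 lower without wild-type untouched replicate 1. Their call was lost without that library (adjusted p = 0.077) and with quantile normalization (adjusted p = 0.051). The replication genes rrm2 (5.45 ± 0.665 against 20.7 ± 0.464 scaled CPM, log2 -1.75 ± 0.14, adjusted p = 3.3e-07) and mcm4 (14.6 ± 0.0457 against 67.8 ± 19, log2 -2.12 ± 0.17, adjusted p = 3.9e-07), the condensin gene smc2 (log2 -1.89 ± 0.15) and hells, a chromatin helicase (log2 -2.59 ± 0.21), fell. col11a1b remained raised (121 ± 28.8 against 2.28 ± 0.901, log2 5.22 ± 0.20), as did nppc (log2 3.64 ± 0.25), and irs2a, an insulin receptor substrate, rose (log2 4.25 ± 0.21). Macrophage genes stayed higher, 22 of 27 higher and 0 lower (25 and 0 adjusted over the list alone), with cd74a at 629 ± 106 against 188 ± 8.11. The median was 1.43 (adjusted p = 1.9e-11). The fibroblast list had 33 of 41 higher and 0 lower (33 and 0 adjusted over the list alone), with mdka 4.52-fold and fn1a 4.56-fold up. The median was 0.91 (adjusted p = 3.4e-19). Oxidative phosphorylation had 1 of 91 higher and 46 lower (2 and 57 adjusted over the list alone, 1 and 29 with pairs averaged), with ndufa4 at 694 ± 41.9 against 1672 ± 157. The median was -0.43 (adjusted p = 1.2e-11), with 10 lower without wild-type 14 dpi replicate 2. Sarcomere genes did not pass as a list (adjusted p = 0.83), and their median and mean differed in sign, with unc45b lower (log2 -1.34 ± 0.18) and tcap, which binds titin at the Z disc, higher (log2 1.2 ± 0.20). 1446 genes were higher and 1268 lower, 2714 together (1845 with the pairs averaged, and 1534 without wild-type 14 dpi replicate 2).

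The mutant time course asks the same of kita/kitb mutants. Its untouched pair had high neutrophil and low cell cycle transcripts (median log2 3.20 and -1.06 against wild type). At 2 dpi, in libraries of another lane, col11a1b stood at 239 ± 5.17 against 0.847 ± 0.155 scaled CPM in untouched mutants (log2 7.02 ± 0.20, adjusted p = 4.9e-13), and fn1a (3668 ± 131 against 84.3 ± 4.28, log2 5.43 ± 0.15, adjusted p = 3.5e-13) and the apolipoprotein gene apoc1l (log2 5.31 ± 0.34) rose. The lysozyme gene lyz fell (2.80 ± 0.0543 against 118 ± 5.92, log2 -4.96 ± 0.36, adjusted p = 1.6e-08), with mmp13a, a collagenase gene (log2 -4.12 ± 0.45), and s1pr4, a leukocyte sphingosine receptor gene (log2 -3.89 ± 0.22). Cell cycle genes rose, 79 of 82 higher and 0 lower (79 and 0 adjusted over the list alone, 67 and 0 with pairs averaged), such as top2a (104 ± 1.0 against 4.71 ± 0.645, log2 4.20 ± 0.14) and cdk1, the mitotic kinase gene (log2 4.07 ± 0.19). The median was 1.92 (adjusted p = 3.2e-28). Epicardium and fibroblast genes had 35 of 41 higher and 0 lower (36 and 0 adjusted over the list alone, 31 and 0 with pairs averaged), with postnb 10.7-fold up. The median was 1.31 (adjusted p = 1.8e-13). Macrophage genes had 21 of 27 higher and 0 lower (21 and 0 adjusted over the list alone, 13 and 0 with pairs averaged), among them apoeb, an apolipoprotein E gene (log2 4.81 ± 0.20). The median was 1.34 (adjusted p = 7.8e-06). 2999 genes were higher and 2723 lower, 5722 together, and 3186 with the near-identical pairs averaged.

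Neutrophil genes fell from the untouched mutant level by 2 dpi, 1 of 15 higher and 10 lower (1 and 10 adjusted over the list alone, 0 and 9 with pairs averaged), with the myeloperoxidase gene mpx at 3.98 ± 0.133 against 63.1 ± 1.37 scaled CPM (log2 -3.68 ± 0.36). The median was -1.2 (adjusted p = 5.3e-04). Oxidative phosphorylation had 2 of 91 higher and 87 lower (2 and 88 adjusted over the list alone, 1 and 85 with pairs averaged), with cox5ab 5.31-fold and cox8b 5.64-fold lower. The median was -1.58 (adjusted p = 3.1e-31). Genes of fatty acid oxidation had 0 of 26 higher and 25 lower (0 and 25 adjusted over the list alone, 0 and 22 with pairs averaged), such as acadl (53.4 ± 0.133 against 264 ± 9.16). The median was -1.51 (adjusted p = 1.0e-13). Sarcomere genes had 2 of 26 higher and 18 lower (2 and 18 adjusted over the list alone, 0 and 14 with pairs averaged), including the cardiac myosin light chain genes myl7 (8038 ± 212 against 23796 ± 763) and cmlc1 (3444 ± 232 against 10331 ± 325). The median was -0.91 (adjusted p = 1.9e-05). Ribosomal protein genes had 5 of 89 higher and 64 lower (5 and 66 adjusted over the list alone, 2 and 41 with pairs averaged), such as rplp2 (log2 -1.62 ± 0.15) and rps15 (log2 -1.35 ± 0.14). The median was -0.56 (adjusted p = 1.2e-09).

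In mutants at 5 dpi col11a1b (142 ± 15.1 against 0.847 ± 0.155 scaled CPM, log2 6.27 ± 0.20, adjusted p = 3.5e-12), postnb (1756 ± 211 against 57.3 ± 2.80, log2 4.91 ± 0.15) and f13a1a.1 (log2 5.33 ± 0.44) rose. il6, the interleukin-6 gene (log2 -4.20 ± 0.33), mmp13a (9.10 ± 6.97 against 240.5 ± 9.12, log2 -4.78 ± 0.45, adjusted p = 5.0e-07) and csf3b, a granulocyte growth factor gene (log2 -2.83 ± 0.30), fell. Cell cycle genes had 66 of 82 higher and 3 lower (67 and 3 adjusted over the list alone, 52 and 2 with pairs averaged), with the nucleotide synthesis genes tk1 (log2 1.88 ± 0.14) and rrm2 (log2 1.72 ± 0.14). The median was 0.85 (adjusted p = 7.0e-13). Fibroblast genes had 35 of 41 higher and 2 lower (36 and 2 adjusted over the list alone, 34 and 0 with pairs averaged), with lum, the lumican gene, at 190.0 ± 0.382 against 13.1 ± 1.0. The median was 1.45 (adjusted p = 5.2e-16). Neutrophil genes lay far below untouched mutants, 0 of 15 higher and 13 lower (0 and 13 adjusted over the list alone, 0 and 13 with pairs averaged), with lyz at 8.35 ± 1.61 against 118 ± 5.92. The median was -2.54 (adjusted p = 1.4e-06). Ribosomal protein genes rose, 76 of 89 higher and 4 lower (79 and 6 adjusted over the list alone, 29 and 4 with pairs averaged), for example rpl22l1 (log2 0.93 ± 0.15). The median was 0.47 (adjusted p = 4.5e-08), with 37 higher without mutant 5 dpi replicate 1. Macrophage (adjusted p = 0.85), inflammatory (adjusted p = 0.081), oxidative phosphorylation (adjusted p = 0.36), fatty acid oxidation (adjusted p = 0.47) and sarcomere genes (adjusted p = 0.30) did not pass as lists, and the median and mean of the macrophage list differed in sign. mpeg1.1 rose (log2 1.98 ± 0.22), while the granulin gene grna (log2 -2.15 ± 0.31) and tcap (log2 -1.60 ± 0.20) fell. 2836 genes were higher and 2763 lower, 5599 together, and 3647 with the pairs averaged.

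At 7 dpi, the mutant comparison with the fewest calls of the 4 times, col11a1b (147 ± 4.94 against 0.847 ± 0.155 scaled CPM, log2 6.33 ± 0.20, adjusted p = 7.9e-12), lama1 (19.1 ± 0.679 against 0.120 ± 0.00999) and thbs4b, a thrombospondin gene (71.8 ± 2.19 against 3.38 ± 0.186, log2 4.06 ± 0.25), rose. s1pr4 (log2 -3.79 ± 0.22) and mmp13a (18.9 ± 2.2 against 240.5 ± 9.12, log2 -3.61 ± 0.45, adjusted p = 3.6e-05) fell. Fibroblast genes had 34 of 41 higher and 0 lower (35 and 0 adjusted over the list alone, 24 and 0 with pairs averaged), with postnb 16.4-fold and fn1a 8.74-fold up. The median was 1.17 (adjusted p = 2.2e-31). Cell cycle genes had 53 of 82 higher and 2 lower (63 and 2 adjusted over the list alone, 14 and 0 with pairs averaged), such as tk1 (log2 1.54 ± 0.14) and the condensin gene smc4 (log2 1.27 ± 0.13). The median was 0.71 (adjusted p = 5.4e-23), with 31 higher without mutant 7 dpi replicate 2. Neutrophil genes fell, 0 of 15 higher and 10 lower (0 and 11 adjusted over the list alone, 0 and 4 with pairs averaged), with mpx at 8.20 ± 0.647 against 63.1 ± 1.37. The median was -1.72 (adjusted p = 2.1e-10). Oxidative phosphorylation had 1 of 91 higher and 5 lower (1 and 0 adjusted over the list alone, 0 and 0 with pairs averaged). The median was -0.30 (adjusted p = 3.1e-09), with 0 lower without mutant untouched replicate 1. Macrophage (adjusted p = 0.16), inflammatory (adjusted p = 0.13) and sarcomere genes (adjusted p = 0.34) did not pass, with csf1a higher (log2 2.15 ± 0.20) and il6 lower (log2 -2.90 ± 0.33). 964 genes were higher and 627 lower, 1591 together, which dropped to 292 with the pairs averaged. The total was 817 and 799 without mutant untouched replicate 1 or 2, and 751 and 754 without mutant 7 dpi replicate 1 or 2.

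At 14 dpi the steep rises in mutants were col11a1b (117 ± 40.5 against 0.847 ± 0.155 scaled CPM, log2 5.95 ± 0.20, adjusted p = 2.1e-11), f13a1a.1 (557 ± 88.5 against 21 ± 0.126, log2 4.66 ± 0.44) and thbs4b (log2 4.38 ± 0.25). mmp13a (3.10 ± 0.243 against 240.5 ± 9.12, log2 -5.88 ± 0.45, adjusted p = 1.4e-07), atp1b1b, a sodium pump subunit gene (log2 -4.82 ± 0.45), and nmnat1, an enzyme of NAD synthesis (log2 -4.59 ± 0.18), fell. Neutrophil genes all lay below untouched mutants, 0 of 15 higher and 15 lower (0 and 15 adjusted over the list alone, 0 and 15 with pairs averaged), with lyz at 6.70 ± 1.27 against 118 ± 5.92. The median was -2.70 (adjusted p = 5.0e-12). Inflammatory cytokine genes fell, 3 of 24 higher and 15 lower (3 and 15 adjusted over the list alone, 3 and 12 with pairs averaged), with il6 at 0.995 ± 0.467 against 29.4 ± 1.21 and mmp9, a gelatinase gene of the neutrophil list too, at 7.94 ± 3.15 against 165 ± 2.33. The median was -1.36 (adjusted p = 2.1e-05). Cell cycle genes lay above untouched mutants, 38 of 82 higher and 4 lower (39 and 4 adjusted over the list alone, 19 and 3 with pairs averaged), with tk1 (log2 1.15 ± 0.14) and mcm3 (log2 1.31 ± 0.18). The median was 0.46 (adjusted p = 1.9e-05), with 25 higher without mutant untouched replicate 2. The fibroblast list had 29 of 41 higher and 3 lower (30 and 3 adjusted over the list alone, 25 and 2 with pairs averaged), with the decorin gene dcn at 1149.6 ± 53.9 against 346 ± 5.01. The median was 0.78 (adjusted p = 1.4e-10). Ribosomal protein genes fell, 2 of 89 higher and 83 lower (3 and 84 adjusted over the list alone, 1 and 76 with pairs averaged), for example rpl11 (log2 -0.91 ± 0.12). The median was -0.74 (adjusted p = 9.9e-26). Oxidative phosphorylation had 1 of 91 higher and 81 lower (1 and 83 adjusted over the list alone, 1 and 39 with pairs averaged), with cox7c at 117 ± 28.5 against 233 ± 8.99. The median was -0.60 (adjusted p = 1.9e-18), with 50 lower without mutant 14 dpi replicate 2. Macrophage (adjusted p = 0.063) and sarcomere genes (adjusted p = 0.67) did not pass, with cd63, a lysosomal membrane gene (log2 -1.02 ± 0.11), and grn1 (log2 -3.88 ± 0.64) lower. 2322 genes were higher and 1983 lower, 4305 together, and 2170 with the pairs averaged.

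**Figure D2:**
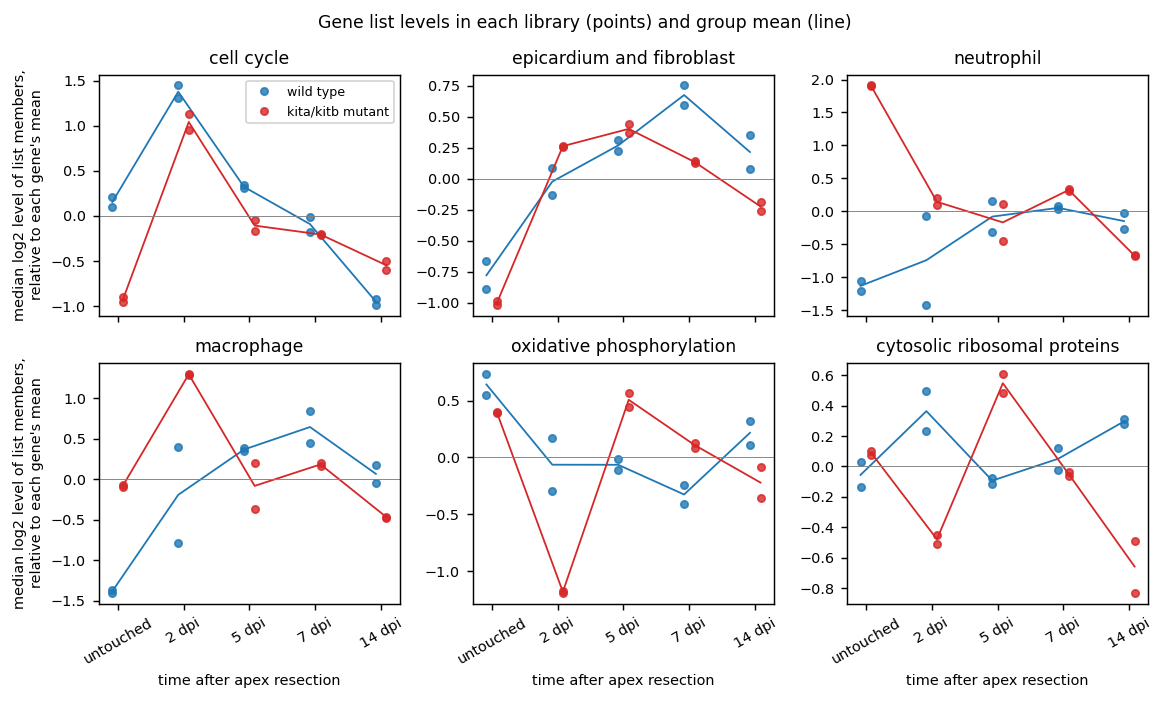
Median log2 level of the members of 6 gene lists in each of the 20 libraries, relative to each gene's mean over all libraries (vertical axis, log2), by time after resection (horizontal axis), with points for libraries and lines through group means, blue for wild type and red for mutants. The cell cycle panel shows untouched mutants below untouched wild type (median log2 difference -1.06), and the neutrophil panel shows them above it (3.20).

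The series design asks whether mutant cardiomyocytes have a proliferation defect, but bulk levels cannot tie cell cycle genes to these cells. Before injury cell cycle genes were lower in mutants, 2 of 82 higher and 62 lower (2 and 65 adjusted over the list alone, 1 and 54 with pairs averaged). The median was -1.06 (adjusted p = 8.9e-20). Erythrocyte genes were lower too, 1 of 15 higher and 8 lower (1 and 8 adjusted over the list alone, 0 and 3 with pairs averaged). The median was -0.70 (adjusted p = 0.041), with 4 lower without mutant untouched replicate 2. Their call was lost with the pairs averaged (adjusted p = 0.053) and without wild-type replicate 1 (adjusted p = 0.12) or mutant replicate 2 (adjusted p = 0.078). The replication genes tk1 (1.71 ± 0.0146 against 9.21 ± 0.873 scaled CPM, log2 -1.91 ± 0.14, adjusted p = 8.3e-08), rrm2 (5.57 ± 0.505 against 20.7 ± 0.464, log2 -1.72 ± 0.14) and mcm6 (9.42 ± 1.38 against 52.2 ± 15, log2 -2.33 ± 0.19, adjusted p = 1.8e-07) were lower. Neutrophil genes were higher in untouched mutants, 14 of 15 higher and 0 lower (14 and 0 adjusted over the list alone, 14 and 0 with pairs averaged), with mpx (63.1 ± 1.37 against 2.15 ± 0.355, log2 4.35 ± 0.36, adjusted p = 2.5e-07), lyz (log2 4.29 ± 0.36) and lect2l, a leukocyte chemotaxis gene (90.5 ± 4.51 against 3.78 ± 0.402). The median was 3.20 (adjusted p = 1.8e-12). Inflammatory cytokine genes were higher too, 20 of 24 higher and 1 lower (20 and 1 adjusted over the list alone, 16 and 1 with pairs averaged). The median was 1.89 (adjusted p = 1.0e-10). They included irg1, which makes itaconate in activated myeloid cells (log2 4.92 ± 0.71), the chemokine gene cxcl12b (log2 1.75 ± 0.14) and ptgs2a (log2 2.35 ± 0.14). mmp13a, held by both lists, was at 240.5 ± 9.12 against 3.30 ± 0.133 (log2 5.81 ± 0.45). Macrophage genes had 17 of 27 higher and 1 lower (18 and 1 adjusted over the list alone, 13 and 1 with pairs averaged), among them cd63 (log2 1.11 ± 0.11) and grna (133 ± 2.02 against 22.2 ± 0.421). The median was 0.69 (adjusted p = 1.2e-06). 2061 genes were higher and 2315 lower in mutants, 4376 together, and 2319 with the pairs averaged.

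Epicardium and fibroblast genes were lower in untouched mutants, 8 of 41 higher and 22 lower (9 and 22 adjusted over the list alone, 6 and 18 with pairs averaged), with postnb lower (57.3 ± 2.80 against 179 ± 0.170 scaled CPM, log2 -1.62 ± 0.15) and wt1b higher (log2 1.64 ± 0.17). The median was -0.49 (adjusted p = 0.021). m17 was higher (77 ± 1.85 against 1.48 ± 0.233, log2 4.98 ± 0.62). ahsa1a, an Hsp90 co-chaperone gene (0.120 ± 0.00999 against 32.7 ± 1.01, adjusted p = 9.9e-08), vsnl1a, a neuronal calcium sensor gene (0.191 ± 0.271 against 20.2 ± 1.61), and gnb5b, a G protein subunit gene (log2 -3.68 ± 0.35), were lower. Fatty acid oxidation (adjusted p = 0.69) and sarcomere genes (adjusted p = 0.19) did not pass as lists, with unc45b lower (log2 -1.79 ± 0.18) and tcap higher (log2 1.08 ± 0.20).

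At 2 dpi energy and ribosomal genes were lower in mutants than in wild type, in libraries that also differed by lane. Oxidative phosphorylation had 1 of 91 higher and 81 lower (1 and 81 adjusted over the list alone, 0 and 75 with pairs averaged), with cox5ab (33.1 ± 1.87 against 167 ± 37.0 scaled CPM, log2 -2.29 ± 0.13, adjusted p = 4.4e-09) and the complex III gene uqcrc2a (28.9 ± 3.19 against 137 ± 23.9, log2 -2.21 ± 0.13). The median was -1.08 (adjusted p = 5.4e-19). Fatty acid oxidation had 4 of 26 higher and 18 lower (4 and 18 adjusted over the list alone, 4 and 18 with pairs averaged), such as slc25a20, the carnitine carrier (log2 -1.3 ± 0.11). The median was -0.84 (adjusted p = 7.0e-04). Ribosomal protein genes had 4 of 89 higher and 68 lower (4 and 72 adjusted over the list alone, 3 and 60 with pairs averaged), with rps15 (160.4 ± 1.68 against 637 ± 91.3) and rplp0 (953 ± 69.4 against 3107 ± 229). The median was -0.84 (adjusted p = 3.2e-13). tnni1d was at 0.254 ± 0.108 against 54.4 ± 29.1 (log2 -5.36 ± 0.39, adjusted p = 3.5e-08), and ahsa1a (log2 -3.30 ± 0.38) and lin7b (log2 -2.77 ± 0.21) were lower. 2983 genes were higher and 3311 lower, 6294 together and 4540 with the pairs averaged.

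Cell cycle genes were lower in mutants at 2 dpi, 1 of 82 higher and 40 lower (1 and 38 adjusted over the list alone, 1 and 31 with pairs averaged), with mcm5 (log2 -1.52 ± 0.16) and ccnb1 (12.8 ± 0.354 against 39 ± 5.06 scaled CPM, log2 -1.51 ± 0.17) lower, while cdc25b, a phosphatase gene that promotes mitosis, was higher (48.7 ± 0.330 against 17.4 ± 2.17, log2 1.44 ± 0.14). The median was -0.42 (adjusted p = 5.9e-05). Macrophage genes were higher, 22 of 27 higher and 0 lower (23 and 0 adjusted over the list alone, 18 and 0 with pairs averaged), among them mafba, a transcription factor of the myeloid lineage (319.8 ± 5.30 against 50.4 ± 15.1, log2 2.67 ± 0.14), and apoeb (log2 2.87 ± 0.20). The median was 1.69 (adjusted p = 2.4e-08). Inflammatory genes were higher, 15 of 24 higher and 0 lower (15 and 0 adjusted over the list alone, 11 and 0 with pairs averaged), with csf1a (log2 2.03 ± 0.20), tnfa (5.56 ± 0.172 against 0.242 ± 0.342), irg1 (log2 4.76 ± 0.71) and the interleukin-1 beta gene il1b (log2 4.40 ± 0.60). The median was 0.95 (adjusted p = 4.2e-04). Without wild-type replicate 1 the medians were 1.97 and 1.42. Without replicate 2 they were 1.19 and 0.66, and the neutrophil list lost its call as higher (median 0.18). Its member ncf1, an oxidase subunit, was higher with all libraries (log2 3.97 ± 0.48). Fibroblast (adjusted p = 0.29) and sarcomere genes (adjusted p = 0.067) did not pass as lists.

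At 5 dpi the energy and ribosomal lists were higher in mutants. Oxidative phosphorylation had 72 of 91 higher and 1 lower (82 and 1 adjusted over the list alone, 64 and 1 with pairs averaged), with ndufa1 (236 ± 20.6 against 113 ± 9.23 scaled CPM, log2 1.06 ± 0.14, adjusted p = 3.8e-05) and cox8b (log2 0.96 ± 0.14). The median was 0.57 (adjusted p = 1.3e-15), with 40 higher without wild-type 5 dpi replicate 1. Fatty acid oxidation had 17 of 26 higher and 0 lower (17 and 0 adjusted over the list alone, 15 and 0 with pairs averaged), with hadh (log2 0.90 ± 0.12) and the acyl-CoA dehydrogenase gene acads (log2 0.90 ± 0.12). The median was 0.45 (adjusted p = 8.6e-05), with 11 higher without wild-type 5 dpi replicate 1. Ribosomal protein genes had 80 of 89 higher and 1 lower (81 and 1 adjusted over the list alone, 74 and 1 with pairs averaged), such as rps28 (log2 1.06 ± 0.15). The median was 0.64 (adjusted p = 1.5e-20). Cell cycle genes were lower, 1 of 82 higher and 40 lower (1 and 40 adjusted over the list alone, 0 and 27 with pairs averaged), with mki67, a marker of cycling cells (5.24 ± 1.41 against 15.4 ± 2.74, log2 -1.40 ± 0.15, adjusted p = 8.0e-06), and slbp, which binds histone messages (log2 -1.71 ± 0.20). The median was -0.41 (adjusted p = 1.4e-07), with 10 lower without wild-type 5 dpi replicate 1. Macrophage genes were lower, 0 of 27 higher and 9 lower (0 and 8 adjusted over the list alone, 0 and 6 with pairs averaged), such as mafba (log2 -1.12 ± 0.14) and mpeg1.2 (29.2 ± 7.45 against 57.0 ± 3.82, log2 -0.96 ± 0.15). The median was -0.41 (adjusted p = 0.021), with 3 lower without mutant 5 dpi replicate 1. That call was lost without mutant 5 dpi replicate 1 (median -0.22, adjusted p = 0.23) and on CPM as deposited (adjusted p = 0.073). 2090 genes were higher and 2126 lower in mutants, 4216 together (3292 with the pairs averaged, 2627 without wild-type and 2574 without mutant 5 dpi replicate 1).

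Among single genes at 5 dpi, coch, which encodes the matrix protein cochlin (11.9 ± 8.23 against 0.155 ± 0.0917 scaled CPM, adjusted p = 9.0e-05), chst1, a carbohydrate sulfotransferase (60.2 ± 3.84 against 5.96 ± 0.332, log2 3.14 ± 0.34), and mlpha, a melanosome transport gene (log2 2.81 ± 0.54), were higher in mutants. tnni1d (0.641 ± 0.0773 against 30.4 ± 15.5, log2 -4.17 ± 0.39, adjusted p = 2.2e-06), vsnl1a (log2 -3.33 ± 0.35), ahsa1a (0.238 ± 0.111 against 10.1 ± 6.09) and unc45b (log2 -1.60 ± 0.18) were lower. Neutrophil (adjusted p = 0.80), inflammatory (adjusted p = 0.99), fibroblast (adjusted p = 0.21) and sarcomere genes (adjusted p = 0.72) did not pass as lists, and the median and mean of the neutrophil list differed in sign. srgn, the serglycin gene of blood cell granules, was higher (471 ± 16.5 against 274 ± 7.67, log2 0.78 ± 0.10).

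At 7 dpi cell cycle genes did not pass as a list between genotypes, with 1 of 82 higher and 8 lower (0 and 2 adjusted over the list alone, 0 and 1 with pairs averaged, median log2 -0.13, adjusted p = 0.079). Without wild-type 7 dpi replicate 1 the members called lower were 2. Without wild-type 7 dpi replicate 2 the list passed as lower (median -0.24, adjusted p = 0.0031). slbp was lower (7.88 ± 1.1 against 17.7 ± 3.50 scaled CPM, log2 -1.06 ± 0.20, adjusted p = 0.0012). Fibroblast genes were lower in mutants, 1 of 41 higher and 24 lower (1 and 26 adjusted over the list alone, 1 and 10 with pairs averaged), with the transferrin gene tfa (159 ± 1.48 against 689.8 ± 270.4, log2 -2.06 ± 0.22) and mdka (849 ± 3.19 against 1936 ± 46.0, log2 -1.19 ± 0.13, adjusted p = 2.5e-05). The median was -0.53 (adjusted p = 4.5e-07). Energy genes were higher. Oxidative phosphorylation had 50 of 91 higher and 2 lower (58 and 2 adjusted over the list alone, 5 and 1 with pairs averaged), with cycsb, a cytochrome c gene (log2 0.78 ± 0.14), and cox8b (585 ± 19.6 against 339 ± 33.4, log2 0.79 ± 0.14). The median was 0.43 (adjusted p = 9.1e-13), with 19 higher without wild-type 7 dpi replicate 1. Fatty acid oxidation had 20 of 26 higher and 1 lower (22 and 1 adjusted over the list alone, 11 and 0 with pairs averaged), with cpt1b, a carnitine palmitoyltransferase of muscle (log2 1.89 ± 0.19). The median was 0.57 (adjusted p = 4.7e-09), with 12 higher without wild-type 7 dpi replicate 1. Sarcomere genes were higher, 9 of 26 higher and 1 lower (9 and 2 adjusted over the list alone, 1 and 0 with pairs averaged), for example myoz2b, a Z-disc protein gene (log2 0.93 ± 0.17). The median was 0.32 (adjusted p = 0.0037), with 3 higher without mutant 7 dpi replicate 1.

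Of single genes at 7 dpi, coch (17.5 ± 1.1 against 0.628 ± 0.254 scaled CPM, log2 3.51 ± 0.48, adjusted p = 9.8e-05), slc25a4 (47.9 ± 2.27 against 5.64 ± 5.81, log2 3.23 ± 0.55) and erich3 (log2 3.20 ± 0.32) were higher in mutants. ahsa1a (0.158 ± 0.143 against 10.6 ± 7.90, adjusted p = 3.5e-05), gnb5b (2.51 ± 0.834 against 28.7 ± 10.2) and f13a1a.1 (80.5 ± 0.140 against 758 ± 562, log2 -2.99 ± 0.44) were lower, as were apoeb (log2 -1.26 ± 0.20) and the cathepsin gene ctsba (log2 -0.84 ± 0.15) of the macrophage list. Neutrophil (adjusted p = 0.15), inflammatory (adjusted p = 0.77) and ribosomal protein genes (adjusted p = 0.21) did not pass as lists. 1432 genes were higher and 1532 lower, 2964 together, which fell to 847 with the pairs averaged. The total was 1786 without wild-type 7 dpi replicate 1, and 1557 and 1560 without mutant 7 dpi replicate 1 or 2.

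At 14 dpi cell cycle genes were higher in mutants than in wild type, 34 of 82 higher and 1 lower (37 and 1 adjusted over the list alone, 27 and 0 with pairs averaged). The median was 0.36 (adjusted p = 5.4e-08), with 22 higher without wild-type 14 dpi replicate 1. The replication genes mcm4 (38.8 ± 6.40 against 14.6 ± 0.0457 scaled CPM, log2 1.35 ± 0.17, adjusted p = 3.4e-05) and mcm3 (15.3 ± 0.352 against 5.51 ± 0.0981, log2 1.32 ± 0.18, adjusted p = 5.6e-05) and uhrf1, which maintains DNA methylation after replication (log2 1.14 ± 0.14), were higher. Ribosomal protein genes were lower, 3 of 89 higher and 80 lower (6 and 82 adjusted over the list alone, 3 and 79 with pairs averaged), with rpl9 (559.6 ± 68.2 against 1386 ± 33.8, log2 -1.31 ± 0.12) and rps15 (222 ± 51.0 against 588 ± 39.8, log2 -1.42 ± 0.14). The median was -0.98 (adjusted p = 2.1e-34). By symbol that list of 89 holds 6 kinase genes of ribosomal protein S6, which are not ribosomal proteins. Oxidative phosphorylation genes were lower, 0 of 91 higher and 52 lower (0 and 61 adjusted over the list alone, 0 and 33 with pairs averaged), such as ndufb2 (log2 -1.08 ± 0.13). The median was -0.43 (adjusted p = 9.1e-12), with 17 lower without wild-type 14 dpi replicate 1. Macrophage genes were lower, 1 of 27 higher and 12 lower (1 and 14 adjusted over the list alone, 1 and 9 with pairs averaged), among them cd74a (289 ± 56.2 against 629 ± 106, log2 -1.13 ± 0.18). The median was -0.61 (adjusted p = 5.9e-04), with 3 lower without wild-type 14 dpi replicate 2. vim, the vimentin gene, was lower (104 ± 5.59 against 204 ± 21.4, log2 -0.96 ± 0.13), with tnni1d (0.692 ± 0.119 against 47.8 ± 30.6, log2 -4.69 ± 0.39, adjusted p = 1.9e-06), ahsa1a (log2 -3.93 ± 0.38) and smyd1b, a methyltransferase gene (log2 -1.83 ± 0.26). itsn1, a scaffold gene of endocytosis (1169 ± 192 against 64.4 ± 3.62, log2 4.15 ± 0.19, adjusted p = 1.5e-09), coch (log2 3.23 ± 0.48) and erich3 (log2 2.69 ± 0.32) were higher. 1767 genes were higher and 1620 lower in mutants, 3387 together (2501 with the pairs averaged, and 2069 without wild-type 14 dpi replicate 1).

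**Figure D3:**
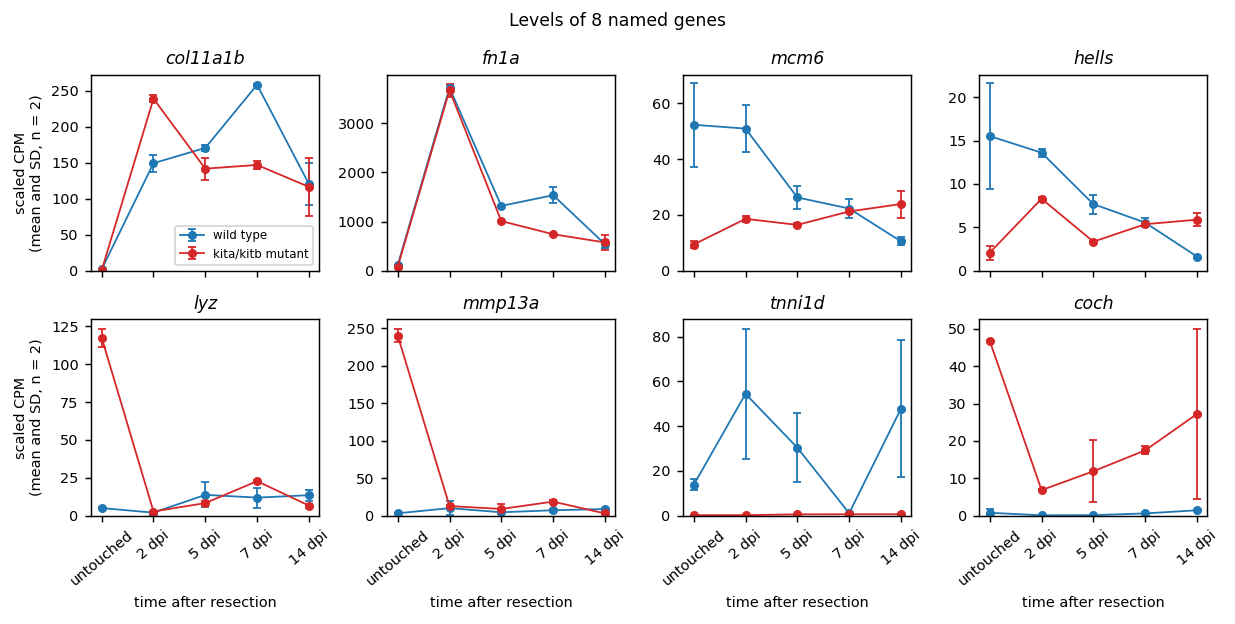
Levels of 8 named genes (vertical axes, scaled CPM, mean and SD of 2 libraries) by time after resection (horizontal axes), blue for wild type and red for kita/kitb mutants. lyz stands at 118 ± 5.92 against 5.08 ± 0.922 and mcm6 at 9.42 ± 1.38 against 52.2 ± 15 in untouched mutants against untouched wild type.

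The last set asks whether the response to resection differed between genotypes, as the mutant log2 change from untouched minus the wild-type one (larger means more positive). An additive run difference cancels at 5, 7 and 14 dpi if lane 8 mutants shared a run, but not at 2 dpi (lane 7). At 2 dpi f13a1a.1 (log2 4.97 ± 0.62, adjusted p = 2.0e-05) and znfl2a (log2 4.14 ± 0.77) had larger responses in mutants, and mmp13a (log2 -5.22 ± 0.64, adjusted p = 1.9e-05) and mmp9 (log2 -4.67 ± 0.62, adjusted p = 3.5e-05) smaller ones. Cell cycle genes had larger responses, 40 of 82 higher and 6 lower (41 and 7 adjusted over the list alone, 15 and 2 with pairs averaged), such as tk1 (log2 2.18 ± 0.20) and smc2 (log2 1.65 ± 0.21), from a lower baseline. The median was 0.59 (adjusted p = 2.8e-05), with 25 higher without wild-type untouched replicate 2. Oxidative phosphorylation genes had smaller responses, 0 of 91 higher and 68 lower (0 and 71 adjusted over the list alone, 0 and 41 with pairs averaged), among them cox5ab (log2 -1.63 ± 0.19). The median was -0.84 (adjusted p = 2.8e-15). Ribosomal protein genes had 2 of 89 higher and 76 lower (2 and 77 adjusted over the list alone, 2 and 60 with pairs averaged), such as rpl10 (log2 -1.73 ± 0.18). The median was -1.06 (adjusted p = 1.3e-20). Neutrophil genes had 0 of 15 higher and 10 lower (0 and 11 adjusted over the list alone, 0 and 7 with pairs averaged), with mpx (log2 -4.42 ± 0.51). The median was -1.25 (adjusted p = 4.6e-05). 2246 genes had larger and 2215 smaller responses, 4461 together, and 2093 with the pairs averaged.

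At 5 dpi responses of oxidative phosphorylation genes were higher in mutants, 77 of 91 higher and 0 lower (79 and 0 adjusted over the list alone, 42 and 0 with pairs averaged), such as ndufa4 (log2 1.26 ± 0.19, adjusted p = 1.9e-04). The median was 0.81 (adjusted p = 4.0e-16). Cell cycle responses were larger from the lower baseline, 42 of 82 higher and 4 lower (44 and 5 adjusted over the list alone, 32 and 3 with pairs averaged), with tk1 (log2 1.68 ± 0.20, adjusted p = 2.7e-05) and the primase gene prim1 (log2 1.64 ± 0.21). The median was 0.65 (adjusted p = 7.3e-07). Ribosomal protein genes had 46 of 89 higher and 3 lower (61 and 3 adjusted over the list alone, 2 and 1 with pairs averaged), with rpl38 (log2 0.81 ± 0.19). The median was 0.50 (adjusted p = 4.5e-08), with 6 higher without mutant 5 dpi replicate 1. From the high mutant baseline, responses of the myeloid lists were smaller. Neutrophil genes had 0 of 15 higher and 13 lower (0 and 13 adjusted over the list alone, 0 and 13 with pairs averaged), with mpx (log2 -4.84 ± 0.51). The median was -3.91 (adjusted p = 1.9e-09). Macrophage genes had 0 of 27 higher and 18 lower (0 and 18 adjusted over the list alone, 0 and 14 with pairs averaged), with mpeg1.2 (log2 -2.25 ± 0.21), grn1 (log2 -5.74 ± 0.91, adjusted p = 2.6e-04) and grn2 (log2 -6.01 ± 1.02). The median was -1.40 (adjusted p = 2.4e-08). Inflammatory genes had 0 of 24 higher and 18 lower (0 and 19 adjusted over the list alone, 0 and 12 with pairs averaged), with irg1 (log2 -5.66 ± 1.0, adjusted p = 6.0e-04) and timp2b, a metalloproteinase inhibitor gene (log2 -3.06 ± 0.28). The median was -1.78 (adjusted p = 3.5e-09). chst1 (log2 3.95 ± 0.49, adjusted p = 3.3e-05), cyp2ad2 (log2 3.69 ± 0.38) and ankrd9 (log2 3.43 ± 0.22) had larger responses. 1940 genes had larger and 1874 smaller responses, 3814 together, and 1864 with the pairs averaged.

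At 7 dpi cell cycle responses were larger in mutants from the lower baseline, while levels did not pass between genotypes. Of these responses, 45 of 82 were higher and 2 lower (53 and 3 adjusted over the list alone, 27 and 0 with pairs averaged), with tk1 (log2 2.18 ± 0.20, adjusted p = 4.7e-06) and rrm2 (log2 1.99 ± 0.19). The median was 0.86 (adjusted p = 3.1e-17). Those of oxidative phosphorylation were higher too, 53 of 91 higher and 0 lower (71 and 0 adjusted over the list alone, 2 and 0 with pairs averaged), such as ndufa4 (log2 1.24 ± 0.19). The median was 0.68 (adjusted p = 2.0e-16), with 25 higher without wild-type untouched replicate 2. Neutrophil genes had 0 of 15 higher and 13 lower (0 and 13 adjusted over the list alone, 0 and 9 with pairs averaged), with mpx (log2 -4.76 ± 0.51). The median was -2.86 (adjusted p = 3.6e-12). Macrophage genes had 0 of 27 higher and 19 lower (0 and 23 adjusted over the list alone, 0 and 11 with pairs averaged), with cd63 (log2 -1.34 ± 0.16) and the leukocyte actin-bundling gene lcp1 (log2 -2.58 ± 0.34). The median was -1.25 (adjusted p = 2.7e-13). tnni1d (log2 3.19 ± 0.56, adjusted p = 9.5e-04) and slc4a1a, the anion exchanger of red cells (log2 2.77 ± 0.38, adjusted p = 1.5e-04), had larger responses, and grn1 (log2 -5.05 ± 0.91) and mmp9 (log2 -5.04 ± 0.62) smaller ones. 1003 genes had larger and 1044 smaller responses, 2047 together, which fell to 418 with the pairs averaged. The total was 1310 and 1340 without mutant untouched replicate 1 or 2, and 1311 and 1304 without mutant 7 dpi replicate 1 or 2.

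At 14 dpi the cell cycle list had its largest difference in response among the 4 times, again from the lower mutant baseline, 63 of 82 higher and 1 lower (66 and 1 adjusted over the list alone, 55 and 1 with pairs averaged). The median was 1.31 (adjusted p = 9.1e-24). mcm6 (log2 3.43 ± 0.27, adjusted p = 4.3e-07), mcm3 (log2 3.26 ± 0.25), hells (log2 3.76 ± 0.30, adjusted p = 4.3e-07) and tk1 (log2 2.89 ± 0.20) had larger responses in mutants. Ribosomal protein genes had smaller ones, 2 of 89 higher and 82 lower (2 and 84 adjusted over the list alone, 0 and 81 with pairs averaged), such as rpl30 (log2 -1.44 ± 0.19). The median was -1.11 (adjusted p = 7.0e-30). Neutrophil genes all had smaller responses, 0 of 15 higher and 15 lower (0 and 15 adjusted over the list alone, 0 and 14 with pairs averaged), with lyz (log2 -5.20 ± 0.52). The median was -3.61 (adjusted p = 1.1e-12). Macrophage genes had 0 of 27 higher and 20 lower (0 and 23 adjusted over the list alone, 0 and 13 with pairs averaged), among them cd63 (log2 -1.48 ± 0.16). The median was -1.39 (adjusted p = 1.1e-09), with 13 lower without wild-type 14 dpi replicate 2. grn1 (log2 -7.38 ± 0.91, adjusted p = 1.9e-05), mmp13a (log2 -7.08 ± 0.64, adjusted p = 1.2e-06) and mmp9 (log2 -6.71 ± 0.62) had smaller responses. 1915 genes had larger and 1710 smaller responses, 3625 together, and 2168 with the pairs averaged.

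**Figure D4:**
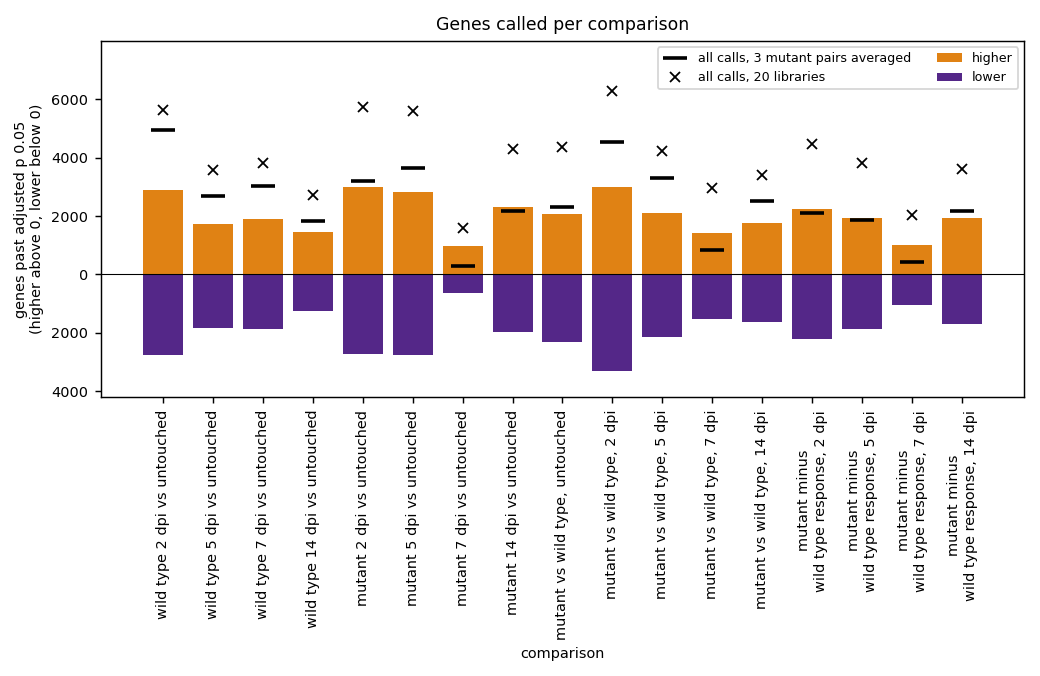
Genes past an adjusted p of 0.05 in each of the 17 comparisons (horizontal axis), as a number of genes (vertical axis), with bars above 0 for higher and below 0 for lower, crosses for the total and dashes for the total with the 3 near-identical mutant pairs averaged. The totals lie between 1591 and 6294, and averaging lowers each of them.

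Across genes, the correlation of the wild-type with the mutant log2 response over 10914 genes was 0.486 at 2 dpi, 0.299 at 5 dpi, 0.285 at 7 dpi and -0.0483 at 14 dpi. Genes are not independent replicates, so no p is given. Of the genes called in both genotypes, 77.2% of 3419 changed in the same direction at 2 dpi, 78.2% of 2101 at 5 dpi, 76.1% of 923 at 7 dpi and 47.0% of 1426 at 14 dpi. With the pairs averaged these were 85.2% of 1950, 83.4% of 1184, 88.4% of 224 and 50.0% of 598. Between genotypes, 147 genes differed in the same direction at all 5 times, 85 higher and 62 lower in mutants, and 60 of them did so with the 3 mutant pairs averaged.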

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

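The tests on runs, on other cells and on an exchange of libraries were chosen only after the result was seen. These values were picked out because a test of the difference itself, mutant response minus wild-type response in limma or camera, passed an adjusted p of 0.05. With an estimated correlation camera called 0 lists.

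At 2 dpi 4461 genes had a different response. The difference in median log2 response was 0.59 for cell cycle genes, -0.84 for oxidative phosphorylation, -1.25 for neutrophil, -0.58 for inflammatory cytokine and -1.06 for ribosomal protein. In log2, the response was higher in mutants for krt5 (7.79), f13a1a.1 (4.97), znfl2a (4.14), apoeb (3.91), elnb (3.47), irf1b (3.37), fosb (2.86), apoc1l (2.77), tk1 (2.18), postnb (2.18), mafba (1.99), unc45b (1.97), smc2 (1.65), cd36 (1.63), col11a1b (1.48), top2a (1.42), mpeg1.1 (1.21), myom1a (1.01), cdk1 (0.86), nr4a1 (0.74) and tek (0.59), and lower for uqcrc1 (-0.73), psma5 (-0.82), cmlc1 (-0.90), acadl (-0.98), wt1b (-1.03), cd63 (-1.05), ccnb1 (-1.15), acadm (-1.17), rplp2 (-1.43), cox5ab (-1.63), cox8b (-1.67), rpl10 (-1.73), ptgs2a (-1.82), rps15 (-1.82), psma6l (-1.84), lipg (-2.13), lyz (-3.92), s1pr4 (-4.07), mpx (-4.42), mmp9 (-4.67) and mmp13a (-5.22). Without wild-type 2 dpi replicate 1 the inflammatory value was -0.56 (adjusted p = 0.31), and without replicate 2 it was -0.95. Its call was also lost with quantile normalization (adjusted p = 0.054), no filter (-0.32, adjusted p = 0.058) and a filter of CPM 5 (adjusted p = 0.072). krt5 was at 4.49 without wild-type untouched replicate 2, and its call was lost with the pairs averaged (adjusted p = 0.078).

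At 5 dpi 3814 genes had a different response. The difference in median log2 response was 0.65 for cell cycle genes, 0.81 for oxidative phosphorylation, -1.40 for macrophage, -3.91 for neutrophil, -1.78 for inflammatory cytokine and 0.50 for ribosomal protein. In log2, the response was higher in mutants for chst1 (3.95), cyp2ad2 (3.69), ankrd9 (3.43), f13a1a.1 (3.04), ctrb1 (2.60), postnb (2.06), tk1 (1.68), cox4i2 (1.66), prim1 (1.64), rrm2 (1.33), ndufa4 (1.26), lum (1.26), cox5ab (1.1), etfb (0.99), cpt2 (0.90), rpl38 (0.81), rps23 (0.78), uqcrc1 (0.74), tek (0.66), rplp2l (0.64) and rpl22l1 (0.62), and lower for psmb9a (-0.82), tcap (-0.86), socs1a (-1.70), ptgs2a (-2.05), psmb8a (-2.23), mpeg1.2 (-2.25), timp2b (-3.06), csf3b (-3.41), il6r (-3.91), grna (-4.15), il6 (-4.21), nppc (-4.24), mpx (-4.84), lyz (-4.84), mmp13a (-5.16), irg1 (-5.66), grn1 (-5.74) and grn2 (-6.01).

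At 7 dpi 2047 genes had a different response. The difference in median log2 response was 0.86 for cell cycle genes, 0.68 for oxidative phosphorylation, -1.25 for macrophage, -2.86 for neutrophil, -1.82 for inflammatory cytokine and -0.25 for ribosomal protein. In log2, the response was higher in mutants for tnni1d (3.19), ctrb1 (3.15), slc4a1a (2.77), slc25a4 (2.39), mcm6 (2.27), tk1 (2.18), rrm2 (1.99), csrp3 (1.60), cpt2 (1.32), thbs4b (1.3), smc4 (1.26), ndufa4 (1.24), tek (1.15), ndufs4 (1.09), unc45b (1.04), cox5ab (1.0), uqcrc1 (0.92) and postnb (0.66), and lower for cd74a (-0.86), mdka (-1.02), b2m (-1.09), mpeg1.1 (-1.1), cd74b (-1.27), csf1a (-1.33), cd63 (-1.34), wt1b (-2.15), lcp1 (-2.58), ptgs2a (-2.75), il6 (-3.22), scpp8 (-3.65), nppc (-4.08), mmp13a (-4.53), s1pr4 (-4.71), mpx (-4.76), grn2 (-4.81), mmp9 (-5.04) and grn1 (-5.05). The ribosomal value was -0.15 and -0.16 without replicate 1 of untouched or 7 dpi wild type. The call of ctrb1 was lost without any 1 of 7 of the 8 libraries, all but wild-type 7 dpi replicate 2 (adjusted p from 0.064 to 0.15). With the pairs averaged the calls of ctrb1 and grn2 were lost (adjusted p = 0.21 and 0.079).

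At 14 dpi 3625 genes had a different response. The difference in median log2 response was 1.31 for cell cycle genes, -0.18 for oxidative phosphorylation, -1.39 for macrophage, -3.61 for neutrophil, -2.16 for inflammatory cytokine and -1.11 for ribosomal protein. In log2, the response was higher in mutants for hells (3.76), ctrb1 (3.55), mcm6 (3.43), mcm3 (3.26), mcm4 (3.16), krt97 (3.05), tk1 (2.89), smc2 (2.55), rrm2 (2.37), f13a1a.1 (2.11), cd36 (2.1), unc45b (1.86), myom1a (1.67), stab1 (1.41), postnb (1.3), ndufa4 (0.97) and dcn (0.53), and lower for mdka (-0.58), rpl11 (-1.09), smyd1b (-1.3), rpl10 (-1.32), ndufb3 (-1.32), rpl30 (-1.44), cd63 (-1.48), cd74a (-1.50), cd74b (-1.70), csf1a (-1.76), tcap (-2.30), ptgs2a (-2.51), lcp1 (-2.79), atp1b1b (-2.95), irs2a (-2.96), il6 (-3.42), nppc (-3.74), nmnat1 (-4.97), mpx (-5.05), lyz (-5.20), mmp9 (-6.71), mmp13a (-7.08) and grn1 (-7.38). ctrb1 had an adjusted p of 0.051 without wild-type 14 dpi replicate 1, and 0.053 with the pairs averaged. The wild-type change of krt97, -3.01, was -1.41 (adjusted p = 0.12) without wild-type untouched replicate 2. The oxidative phosphorylation value was -0.07, -0.06 and -0.07 (adjusted p = 0.21, 0.24 and 0.28) without wild-type untouched replicate 1, wild-type 14 dpi replicate 1 or mutant 14 dpi replicate 2, and -0.33 to -0.30 without the other replicate of each. Its call was also lost with quantile normalization (-0.08, adjusted p = 0.37), and it was 0.01 on CPM as deposited.

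Cell cycle genes were lower in untouched mutants (median log2 -1.06) and higher at 14 dpi (0.36). A fixed shift between the runs cannot give both signs. The response difference (1.31 at 14 dpi) restates that pattern. Spread understated by the near-identical pairs is argued against by the 54 members still called lower with those pairs averaged. Fewer erythroid cells in untouched mutants remain possible: the erythrocyte list was at -0.701, and hbaa1, a hemoglobin gene, at 2069 against 6730 scaled CPM, which could account for part of the difference. Genotype stays open as untested, as does a run effect that differs between times.

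Neutrophil genes were higher in untouched mutants, 14 of 15 tested, of which mmp9 and mmp13a are in the inflammatory list too. A fixed run shift is argued against by 5, 7 and 14 dpi in lane 8, where the highest genotype median was 0.199. It was 0.92 at 2 dpi in another lane (0.18 without wild-type replicate 2). Also argued against is an exchange with an injured group, by the fibroblast median of -0.494. An even rise of all other cells is argued against by the endothelium, fibroblast and erythrocyte lists (-0.102 or lower). Fewer cardiomyocytes beside more leukocytes stay open (macrophage list 0.69). More neutrophils in these preparations may be a source, but the 14 raised members are the pattern itself and cannot test it, and their rises differ in size: pnp5a (898 against 97.4 scaled CPM), ncf1 (596 against 71.9), srgn (534 against 339) and lyz (118 against 5.08). No sort or gate is given in the labels, and genotype, handling of the fish and cell isolation stay open, with 2 nearly identical libraries behind the pattern.

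Ribosomal protein genes were lower in mutants at 14 dpi (80 of 89, median log2 -0.98) and 2 dpi but higher at 5 dpi. Library scaling alone is argued against, since at least 77 were called lower at 14 dpi under both other scalings. A deviating library is argued against too, since at least 77 were called lower without any 1 of the 4 libraries. Shares of hsp70 heat shock reads went the other way at these times, not at 7 dpi. Genotype, run and cell isolation stay open.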

How the results depend on the processing

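The tests with edgeR, with the 3 near-identical mutant pairs averaged and without single libraries for lists other than the cell cycle list were chosen only after the result was seen. All 17 counts of genes stayed within 1.5 times their value on CPM as deposited, with quantile normalization, no filter, a filter of CPM 5, a pseudocount of 0.25, a replicate block and edgeR, as did 4 and 4 counts with each genotype alone.

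With the pairs averaged 10 counts moved further, through less power or, if the pairs are repeats, fewer false calls. In mutants against untouched they were 3186 for 5722 at 2 dpi, 3647 for 5599 at 5 dpi, 292 for 1591 at 7 dpi and 2170 for 4305 at 14 dpi. Between genotypes they were 2319 for 4376 untouched and 847 for 2964 at 7 dpi. For the responses they were 2093 for 4461 at 2 dpi, 1864 for 3814 at 5 dpi, 418 for 2047 at 7 dpi and 2168 for 3625 at 14 dpi.

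Without single libraries, where the lone library is assumed to vary like the other groups, 17 of 84 counts moved by over 1.5 times. The ranges were 2146 to 2988 (main 3581) for wild type at 5 dpi, 1534 to 1912 (2714) for wild type at 14 dpi, 751 to 817 (1591) for mutants at 7 dpi, 2574 to 3574 (4216), 1557 to 2189 (2964) and 2069 to 2863 (3387) between genotypes at 5, 7 and 14 dpi, and 1304 to 1851 (2047) for the response at 7 dpi. The cell cycle list between genotypes at 7 dpi ranged from -0.24 to -0.037 and passed only without wild-type 7 dpi replicate 2 (adjusted p = 0.0031). It kept its sign and call in the other 8 genotype and response comparisons.

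On CPM as deposited 3 lists reversed: proteasome genes in wild type at 7 dpi to 2.1e-04 (from -0.23), ribosomal protein genes in mutants at 7 dpi to 0.023 (from -0.13) and oxidative phosphorylation in the response at 14 dpi to 0.013 (from -0.18). That setting shifts all genes: the median log2 of all genes was 0.27, 0.14 and 0.20 in wild type at 2, 5 and 7 dpi, 0.32, 0.13 and 0.24 in mutants at 2, 7 and 14 dpi, -0.17 and 0.18 between genotypes at 5 and 14 dpi, and -0.11 and 0.22 in the response at 5 and 14 dpi. The share of called genes that were higher moved from 51.1 to 74.1%, 48.3 to 72.7% and 50.4 to 75.4% in wild type at 2, 5 and 7 dpi. In mutants it moved from 52.4 to 76.0%, 60.6 to 82.5% and 53.9 to 77.9% at 2, 7 and 14 dpi. Between genotypes it moved from 49.6 to 27.3%, 48.3 to 35% and 52.2 to 76.0% at 5, 7 and 14 dpi, and for the response from 50.9 to 31.7% and 52.8 to 69.3% at 5 and 14 dpi.

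The counts of list members moved by over 1.5 times for 44 of 131 described list values with the pairs averaged, and for 48 without 1 library. Of the medians, calls were lost for 10 with quantile normalization, 5 with a filter of CPM 5, 3 with the pairs averaged, 2 on CPM as deposited, and 1 each with no filter, a pseudocount of 0.25 and a replicate block. Of 362 named gene values, 12 lost calls with the pairs averaged, 2 each on CPM as deposited and with no filter, and 1 each with quantile normalization and mutants alone. Without single libraries 35 of 616 list values and 34 of 1712 gene values lost their call. As selected values they cannot show stability. Causes not shown above were not tested. Replicate numbers had a median correlation of -0.0083 over 45 pairs of groups and mark no pairing. A block of them gave 4261 genes in untouched hearts against 4376. Depth limits genes near the floor of 0.0947 to 0.205 CPM, kitb and kitlgb among them.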

Other observations

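Interferon response genes rose in wild type at 5 dpi, 16 of 23 higher and 0 lower (17 and 0 adjusted over the list alone), with socs1a, a suppressor of cytokine signalling (log2 1.42 ± 0.16). The median was 0.85 (adjusted p = 4.5e-08). They were still raised at 7 dpi, 13 of 23 higher and 1 lower (17 and 1 adjusted over the list alone), with the MHC class I subunit gene b2m (log2 0.87 ± 0.10). The median was 0.73 (adjusted p = 4.8e-06). In mutants against wild type at 5 dpi they were lower, 1 of 23 higher and 10 lower (1 and 11 adjusted over the list alone, 1 and 9 with pairs averaged), such as the transcription factor gene stat1b (log2 -2.01 ± 0.29). The median was -0.70 (adjusted p = 0.0060). Immediate early and dissociation stress genes fell in wild type at 2 dpi, 0 of 35 higher and 27 lower (0 and 28 adjusted over the list alone), with fosb (log2 -2.11 ± 0.14) and nr4a1 (log2 -1.82 ± 0.13). The median was -0.94 (adjusted p = 3.0e-11). They were higher in mutants than in wild type at 2 dpi, 25 of 35 higher and 2 lower (25 and 2 adjusted over the list alone, 22 and 0 with pairs averaged), with fosb (log2 2.06 ± 0.14). The median was 0.75 (adjusted p = 2.1e-07).

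A hypothesis, written before its test, was that genes called in the same direction between genotypes at all 5 times could lie near kita or kitb, as passenger variants of the mutant lines would. Of the 147 genes 125 were matched to a gene order of another zebrafish assembly, and 2 of them (1.60%) lay within 100 annotated genes of either locus, against 117 of 9556 others (1.22%; Fisher exact p = 0.668, two-sided). The result argues against linkage as the source of most of these genes.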
